A study of Mus musculus with 2 samples.

How the data were processed

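Single-cell RNA sequencing was carried out on whole kidney of C57BL/6J mice at postnatal day 2, with 1 library of the control and 1 of the group exposed to maternal diabetes. The labels name 1 kidney and pooled cells, and do not settle whether a library held cells of more than 1 animal. Per the labels' protocols, kidneys were dissociated with trypsin, and the cells were passed through a filter, frozen in serum with dimethyl sulfoxide and processed with the 10x Genomics Chromium 3' kit, which attaches a unique molecular identifier (UMI) to each captured transcript. Cell Ranger 2.2.0 and genome build mm10 (GRCm38) were used, per the submitters' processing notes. The authors deposited, for each library, UMI counts per gene and cell, which are whole numbers with no normalization. They also deposited log2 values made by the authors as the log2 of the count over 1 factor per cell, plus 1, a form checked against the counts; the tool behind the factors is not given in the sources used here. The authors' table of cells, per the file headers, gives the percent of each cell's UMIs from the mitochondrial genome, UMI and gene totals, doublet scores and a cluster number. Each doublet score per cell was computed by the authors before deposit, per the file headers. The authors' 10 clusters per library carry no names and are numbered separately, so they were not used. Criteria by which the authors chose cells and genes are not given in the sources used here.

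All deposited cells were kept, 9071 in the control and 5494 in the exposed library, with 998 to 53726 and 1250 to 54131 UMIs per cell. The count tables hold 97.7% and 97.6% of the UMIs that the authors' table of cells records. Only the 8930 genes listed for both libraries were compared, and these carry 99.4% of the UMIs of each table. A further 660 genes listed for the control and 615 listed for the exposed library were left out, and Xist and Igf2 are not among the shared genes. Cells with over 50% mitochondrial UMIs made up 10.4% of the control (943 cells, 9.77 to 11.0) and 7.88% of the exposed library (433 cells, 7.18 to 8.63). With 1 library per group no p-value, standard error or number of changed genes was computed. The intervals are 95% Clopper-Pearson intervals for shares and Newcombe intervals for differences of shares. Exact Poisson intervals were used for summed UMIs and exact conditional binomial intervals for ratios. All cover counting error only. Intervals for UMIs and ratios treat each UMI as an independent draw and leave out spread between cells. They are too narrow where few cells hold most UMIs of a gene.

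Cells of both libraries were clustered together with scanpy 1.11.5 on Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen by library, 30 principal components, 15 neighbours and the Leiden method (igraph 0.11.9) at resolution 1 were used, without integration. The 25 clusters were named from marker lists of 16 cell classes fixed before the data were examined, as were the gene lists, the rule for named genes, the summary statistics and most alternatives. A marker counted as detected in a cluster when at least 10% of its cells held it at a level at least 2 times that of the other cells, and a name needed 3 detected markers. Stroma-like clusters 2 and 3 had no fixed marker among their 10 leading genes and rest on detected markers. A cluster with equal support for 2 classes carries both names, and 2 clusters stayed unnamed. Doublets were called with Scrublet in each library, which marked 1 control and 4 exposed cells (0.011% and 0.0728%), so the caller did not work here; cells with an authors' hybrid doublet score over 1 (584 control and 277 exposed cells) were left out as an alternative chosen after the data were seen. Macrophage-like and neutrophil-like cells numbered under 100 in a library and were not compared for expression.

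Within each of the 11 compared classes, UMIs were summed per gene and library and scaled to counts per total of the class (CPM). Log2 ratios are of exposed over control CPM with 10 CPM added to each, which understates the change of low genes. A list was summarised by the median log2 ratio of its genes with at least 50 UMIs over both libraries, where at least 5 were measured. Beside each median stand its percentile among 10000 random lists of the same size, matched on expression in 20 bins, and limits from 500 Poisson resamplings of the counts. The 25 lists cover nephron progenitor self-renewal, early nephron differentiation, canonical Wnt targets, the S phase, the G2/M phase, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, hypoxia, oxidative stress and unfolded protein responses, p53 targets and apoptosis, immediate early, heat shock, interferon response, extracellular matrix, insulin and IGF signalling, renin-angiotensin, polyol and hexosamine, sterol and lipid synthesis, proximal tubule transport and metabolism, angiogenic endothelium, haemoglobin (4 shared genes, so given by gene), inflammatory and cytosolic ribosomal protein genes. Up to 4 members per list, those with the largest log2 ratios in size, could be named.

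Named genes were the 10 highest and 10 lowest by log2 ratio in nephron progenitor-like cells, and the 5 highest and 5 lowest in each other class. They were taken from genes with at least 100 UMIs over both libraries and at least 100 CPM in a library, without haemoglobin genes. Genes that differed the same way by at least 0.5 in at least 80% of the classes where they were measured (at least 4) were named once. A few genes that these rules select are not reported here. Genes that define a class by leading its clusters or naming it are given over wider sets of cells, since the clustering selects on them. Gene positions are from the GRCm38 annotation and are counted from 1. For shares of cells with G2/M phase genes, each cell was thinned to 2554 UMIs, the lower quartile over both libraries, and cells with fewer were left out. Values of genes and lists in thinned cells use the same thinning. They therefore differ from the main values in the cells compared as well as in depth. Figures were drawn with matplotlib 3.10.9; other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0.

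The statistics were tested on simulated data drawn from the nephron progenitor-like sums. Each gene's sum was drawn independently as a Poisson value, the model behind the intervals, so coverage near 95% was set in advance. Spread between cells was not simulated, and the coverage of the intervals in the real data was not tested. In a step on 8930 genes, those changed by 1 log2 unit up or down were recovered with medians of 0.88 and -0.91, and genes changed by 2 units with 1.84 and -1.46; the intervals covered the simulated ratio in 96%, 94%, 98% and 94% of these genes. In a step on 6666 genes, 7 of 100 unchanged lists of 15 genes lay outside the middle 95% of random lists, and all 50 lists moved by 0.5 lay above it. Alternatives varied the clustering resolution, the joint clustering, the depth, the scaling (TMM and median-of-ratios factors), the added CPM, the minimum count, the averaging over cells, the authors' log2 values in place of the counts, the doublets and the gene threshold for G2/M phase cells. Chosen after the data were seen were the removal of cells with over 25% mitochondrial UMIs, totals without mitochondrially encoded genes, thinning to 1000 UMIs, the hybrid doublet score and the removal of the 5 cells with most UMIs of a gene.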

Results

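Kidney cells of newborn mice were profiled by droplet single-cell RNA sequencing, a method that tags each captured transcript with a unique molecular identifier (UMI), to ask how maternal diabetes bears on kidney development. The data are 2 libraries, 1 per group. Both came from mice labelled as strain C57BL/6J, a control group and a group exposed to maternal diabetes. The submitters' descriptions speak of pooled cells and of 1 kidney, which leaves open whether each library held cells of a single animal. Both groups were at postnatal day 2, when mouse kidneys still form nephrons. The control library held 9071 cells and 39442253 UMIs over 9590 listed genes, with medians of 3523 UMIs and 1436 genes per cell. The exposed library held 5494 cells and 28381167 UMIs over 9545 genes, with medians of 4346 UMIs and 1730.5 genes per cell. Comparisons used the 8930 genes listed for both libraries. The Y-linked genes were detected in both: Ddx3y stood at 65.7 CPM (its UMIs scaled to a common library total) in the control and 61.7 in the exposed library, Eif2s3y at 78.5 and 90.1, Kdm5d at 17.4 and 17.3, and Uty at 20.4 and 18.5. The X-inactivation transcript Xist was not analysed here, since neither gene list holds it. With 1 library per group no test of the exposure was possible and no difference has a replicate check, so values are given for both libraries. Every 95% interval covers counting error only, and intervals of gene ratios leave out spread between cells.

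The first comparison asked which cell classes each library held. Clustering of both libraries together gave 25 clusters, named from fixed marker genes. Nephron progenitor-like cells, the Six2 and Cited1 expressing cells from which nephrons arise, made up 7.08% of control cells (642 cells, exact binomial interval 6.56 to 7.62) and 7.12% of exposed cells (391 cells, 6.45 to 7.83), a difference within counting error at 0.039 percentage points (-0.81 to 0.914). With each library clustered on its own the shares were 7.40% and 11.7%, a difference of 4.27 points. Differentiating nephron-like cells, defined by Wnt4, Lhx1, Osr2 and Cdh6, made up 11.9% of the control (1075 cells, 11.2 to 12.5) and 14.0% of the exposed library (771 cells, 13.1 to 14.98). That difference of 2.18 points (1.06 to 3.33) lay outside counting error. The largest cluster of this class (795 control and 535 exposed cells) had Wnt4, the progenitor marker Uncx and the mitotic genes Ube2c and Cenpf among its leading genes. In it 8 differentiating nephron and 7 progenitor markers were detected. Cycling progenitors may therefore be counted in this class and be missing from the progenitor-like share. The cluster of this class led by Osr2 and Cdh6 held 245 control and 210 exposed cells (22.8% and 27.2% of the class), and in it 3 differentiating nephron and 5 proximal tubule markers were detected, with Keg1 among its leading genes. A related cluster that carried equal numbers of differentiating nephron and loop of Henle markers, led by Irx1, Cxcl14 and Epcam, held 5.83% and 7.15%, which was 1.32 points more in the exposed library (0.499 to 2.17). No cluster carried both names in 5 of 9 alternative clusterings and filters.

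Among the other classes, pericyte, smooth muscle and renin cell-like cells held 2.79% of the control and 3.49% of the exposed library (difference 0.706 points, 0.127 to 1.32), and macrophage-like cells held 1.18% and 1.64% (0.459 points, 0.0693 to 0.881). The macrophage-like difference was -0.375 points when each library was clustered on its own, where the control cluster (209 cells) also held S100a8 and S100a9 among its leading genes. Proximal tubule-like cells held less of the exposed library (7.23% and 6.32%, -0.916 points, -1.74 to -0.0674), as did intercalated cell-like cells (2.502% and 1.93%, -0.573 points, -1.05 to -0.073). Differences in the remaining named classes lay within counting error: podocyte-like (7.15% and 7.63%), loop of Henle and distal tubule-like (6.43% and 6.79%), ureteric bud and collecting duct-like (5.34% and 5.01%), stroma-like (27.1% and 25.9%), endothelium-like (8.18% and 9.01%) and neutrophil-like cells (1.07% and 0.91%). Unnamed clusters held 6.31% of the control and 3.06% of the exposed library. They were a cluster with a median of 98.1% mitochondrial UMIs (531 and 163 cells) and a small one led by Upk3a, Krt19 and Upk1b (41 and 5 cells). When each library was clustered on its own, the differentiating nephron-like difference was -8.66 points, but clusters with shared leading genes were then named differently: that led by Cxcl14, Irx1 and Epcam was named differentiating nephron-like in the control (439 cells) and loop of Henle and distal tubule-like in the exposed library (368 cells). The differences were then 4.47 points for loop of Henle and distal tubule-like, 0.564 for neutrophil-like and 0.984 for unnamed cells. At a coarser clustering the proximal tubule-like difference became 0.0466 and the differentiating nephron-like one 0.98 points, and in cells thinned before clustering they were -2.27 points for proximal tubule-like, -0.915 for loop of Henle and distal tubule-like and 2.90 for stroma-like cells.

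**Figure D1:**
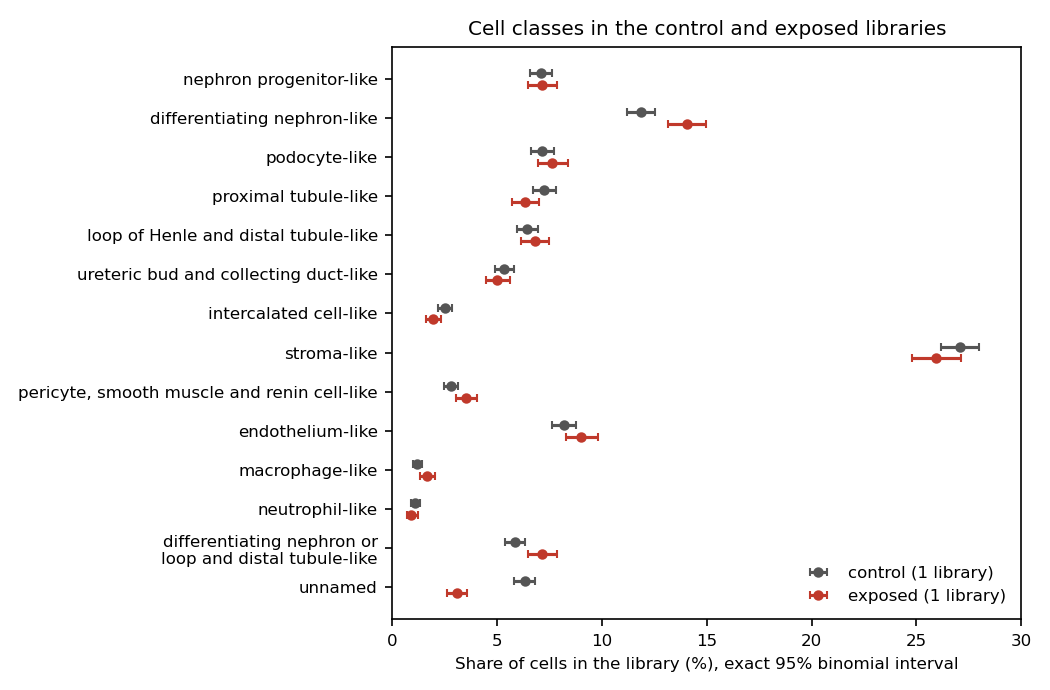
Share of each library's cells (x axis, percent) in each cell class (y axis), as points with exact 95% binomial intervals for counting error, for the control library (grey, 9071 cells) and the exposed library (red, 5494 cells). Nephron progenitor-like cells sit at 7.08% and 7.12%, and differentiating nephron-like cells at 11.9% and 14.0%.

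The second comparison asked which genes differed within the nephron progenitor-like cells, whose leading genes were Cited1, Spock2 and Six2 and also held the heat shock genes Dnajb1 and Dnaja4. Heat shock and immediate early genes were higher in the exposed library, and mitochondrially encoded genes lower. Hspa1a, an inducible chaperone gene (chromosome 17, 34969190 to 34972156, mm10), stood at 3179 CPM in the control and 4872 in the exposed library, a ratio of 1.53 (1.49 to 1.58). The chaperone gene Hsp90aa1 had a ratio of 1.38 (1.33 to 1.43). Jun, a subunit of the transcription factor AP-1 (chromosome 4, 95049034 to 95052222), stood at 1027 and 1516 CPM (ratio 1.48, 1.40 to 1.56). Other genes with high ratios were Phlda1 (1.47), Igfbp4, which encodes a binding protein of insulin-like growth factors (1.46), Mettl9 (1.41) and Id1, a target of BMP signalling (1.40).

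Among the lowest, 8 of 10 genes were encoded by the mitochondrial genome. The complex I subunit gene mt-Nd3 (mitochondrial chromosome, 9459 to 9806) stood at 597 CPM in the control and 231 in the exposed library, a ratio of 0.387 (0.347 to 0.43), followed by mt-Nd1 (0.463), mt-Nd4l (0.541), mt-Cytb (0.544), mt-Co1 and mt-Co2 (both 0.569), and mt-Atp6 and mt-Nd4 (both 0.586). The small heat shock protein gene Cryab (0.38, 0.308 to 0.465) and the actin-binding protein gene Tagln (0.546, 0.437 to 0.678) were lower as well. Mitochondrial transcripts made up 10.0% of this class's UMIs in the control and 5.83% in the exposed library. Cells with over 25% mitochondrial UMIs made up 8.41% of the class in the control and 1.53% in the exposed library, and without them the log2 ratio of mt-Nd3 was -0.83 in place of -1.33 and that of mt-Nd1 -0.39 in place of -1.10, while the other 6 lay between -0.39 (mt-Cytb) and -0.28 (mt-Nd4l).

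**Figure D2:**
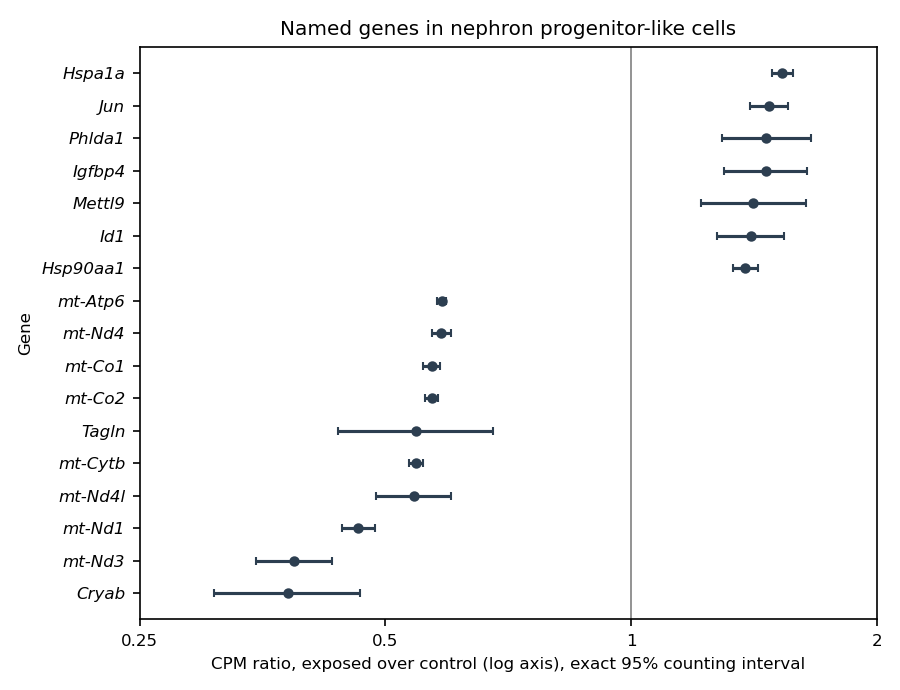
Ratio of CPM, exposed over control (x axis, log scale), with exact 95% counting intervals, for genes named in nephron progenitor-like cells (y axis; 642 control and 391 exposed cells, 1 library each). Hspa1a lies at 1.53 and mt-Nd3 at 0.387, on either side of the line at 1.

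Genes that set the border between progenitors and their progeny were compared over both classes together, the nephrogenic lineage (1717 control and 1162 exposed cells). Cited1, a transcriptional coregulator of uncommitted progenitors (X chromosome, 102247381 to 102252181), stood at 356 CPM in the control and 256 in the exposed library (ratio 0.72, 0.681 to 0.761). Six2, the transcription factor that maintains progenitors (chromosome 17, 85684277 to 85688274), stood at 93.9 and 66.2 CPM (0.705, 0.631 to 0.786). Wnt4, which drives the mesenchymal to epithelial transition (chromosome 4, 137277489 to 137299726), was higher in the exposed library at 489 and 564 CPM (1.15, 1.11 to 1.20), as was the nephric transcription factor gene Pax8 (chromosome 2, 24420560 to 24475599) at 178 and 210 CPM (1.18, 1.10 to 1.27).

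The fixed lists went the same way by count. Cited1 and Six2 belong to the self-renewal list and Wnt4 and Pax8 to the early differentiation list, so the lists are not separate from these genes. In the nephron progenitor self-renewal list, 13 of 17 measured genes were lower in the exposed library, with a median log2 ratio of -0.10 (-0.17 to -0.05), below 99.9% of random lists matched on expression (percentile 0.12). Crym was among them at -0.27, while the progenitor growth factor gene Fgf20 was higher at 0.33. In the early nephron differentiation list, 15 of 18 genes were higher (median 0.12, 0.06 to 0.15, percentile 99.9), among them Osr2 at 0.35 and Cdh6 at 0.23, while Notch1 was lower at -0.24. Of the canonical Wnt targets, 8 of 9 were higher (median 0.17, percentile 99.8), with Sp5 at 0.45, Notum at 0.44 and Myc at 0.42. In progenitor-like cells alone, the medians of the self-renewal and early differentiation lists were -0.03 and -0.02, both inside the middle 95% of random lists. The lineage was composed somewhat differently in the libraries: the cluster led by Osr2 and Cdh6 held 14.3% of its control and 18.1% of its exposed cells, and the progenitor-like cluster 37.4% and 33.6%. With both libraries weighted to the same mix of clusters, the self-renewal median was -0.03 (-0.10 to 0.02), with limits that include 0, and the early differentiation median 0.08 (0.04 to 0.12). The mix alone gave -0.07 for the self-renewal list. At the same mix Cited1 was at -0.36, Six2 at -0.35, Wnt4 at 0.27, Pax8 at 0.23 and Osr2 at 0.08.

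Stress-related and metabolic lists were also read over the nephrogenic lineage. Of the immediate early genes, 14 of 16 were higher (median 0.27, 0.24 to 0.31), led by Klf2 at 0.63, Klf6 at 0.57 and Jun at 0.47. Of the heat shock genes, 9 of 10 were higher (median 0.22, 0.20 to 0.24), with Hspa1a at 0.45 and Hspa1b at 0.39. All 14 measured glycolysis genes were higher (median 0.15, percentile 99.95), including Gpi1 at 0.24 and Ldha at 0.20. Nuclear-encoded oxidative phosphorylation genes were lower in 31 of 36 cases by small amounts (median -0.08), such as Uqcrb at -0.19. The mitochondrially encoded genes were lower in 13 of 13 cases (median -0.39, -0.41 to -0.37), and in 13 of 13 with a median of -0.77 in the progenitor-like cells. Without cells over 25% mitochondrial UMIs these medians were -0.22 and -0.32.

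Other lists with medians beyond the middle 95% of random lists in the nephrogenic lineage were the interferon response (0.28, with H2-K1 at 0.44), the renin-angiotensin system (0.21, with 5 of 5 genes higher), sterol and lipid synthesis (0.18, although Scd2 stood at -0.43), proximal tubule transport and metabolism (0.13, with Keg1 at 0.66 and Slc34a1 at 0.50), the G2/M phase list (-0.11, with Cenpe at -0.72) and the extracellular matrix (-0.08, with Col1a1 at -0.45). The renin-angiotensin system median was 0.07, and that of proximal tubule transport and metabolism was 0.00, when cells were thinned to equal depth and shallower cells left out. Medians inside that range were found for the S phase list (0.03), hypoxia response (0.06), oxidative stress response (-0.04), unfolded protein response (0.04), p53 targets and apoptosis (0.03), insulin and IGF signalling (0.01, although Igfbp4 stood at 0.35 and Igfbp7 at 0.33), polyol and hexosamine pathways (0.03), inflammatory genes (0.00) and cytosolic ribosomal proteins (0.02). Over all classes and lists, 118 of 265 medians lay outside the middle 95% of random lists, where 5% would by chance if genes were independent.

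**Figure D3:**
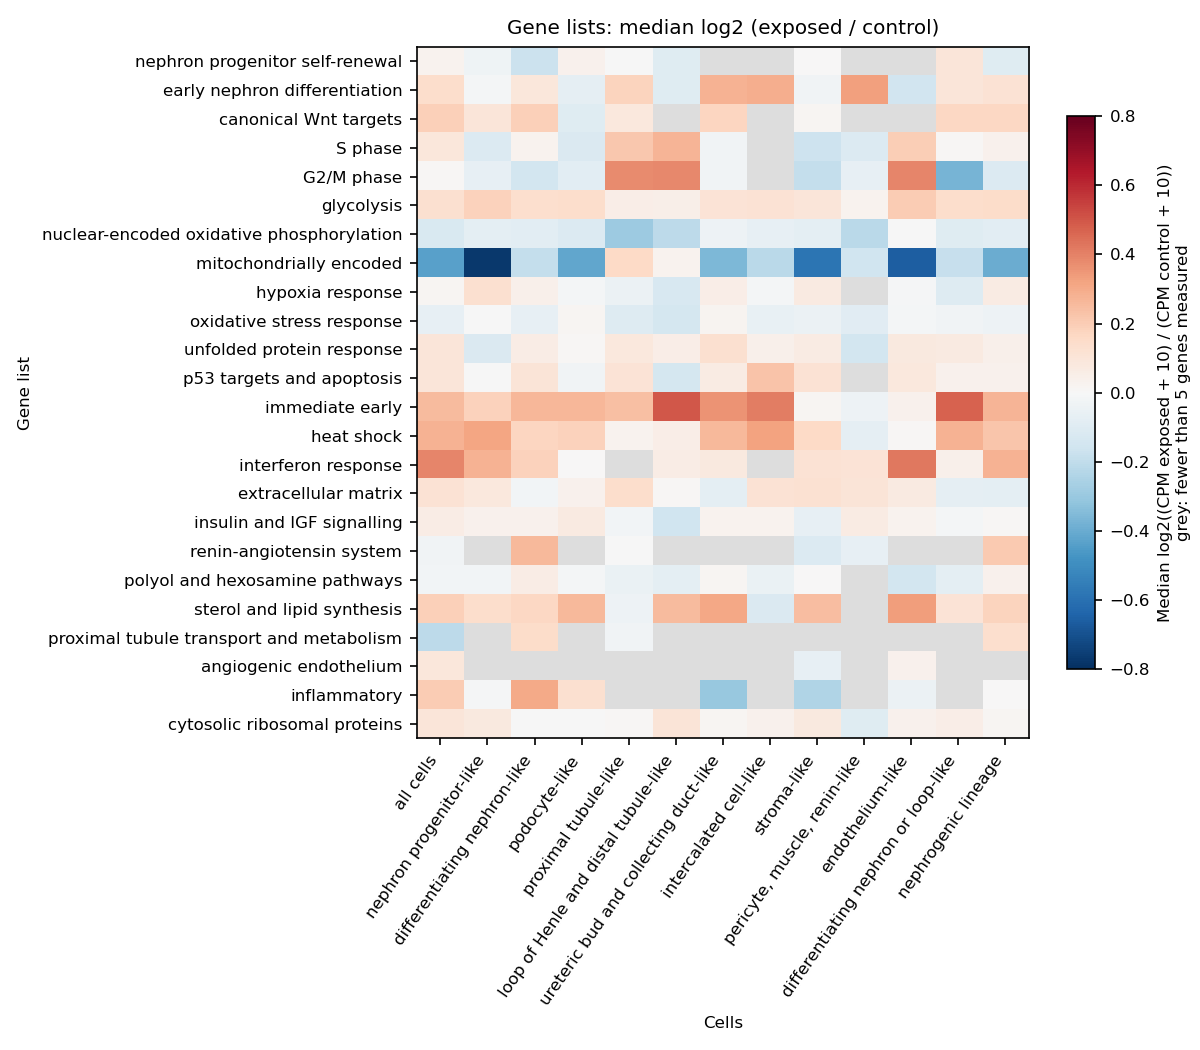
Median log2 ratio of CPM, exposed over control with 10 CPM added to each, for each fixed gene list (y axis) in each set of cells (x axis), as colour from blue (lower in the exposed library) to red (higher); grey marks lists with fewer than 5 measured genes. The mitochondrially encoded list is at -0.77 in nephron progenitor-like cells and 0.16 in proximal tubule-like cells, with -0.32 and -0.26 once cells over 25% mitochondrial UMIs are left out, and the immediate early list at 0.50 in loop of Henle and distal tubule-like cells and 0.03 in endothelium-like cells.

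Differentiating nephron-like cells had higher Krt8, a simple epithelial keratin (ratio 1.58, 1.44 to 1.73), Klf6 (1.56), Id1 (1.497), Hrsp12 (1.46) and Cyr61, a target of YAP signalling (1.44) in the exposed library, and lower mt-Nd3 (0.693), the cotransporter gene Slc12a2 (0.696), Brd3 (0.735) and Tpm2 (0.739). The self-renewal list was lower in 13 of 17 cases here (median -0.17, -0.25 to -0.09). The cluster shared with the loop of Henle had higher Btg2 (1.59), Jun (1.56), Atf3 (1.53), Fosb (1.497) and Fos (1.47), and lower Cryab (0.60), Fxyd2 (0.628), 2810417H13Rik (0.643), the mitotic gene Ube2c (0.648) and Spp1 (0.654). All 20 of its G2/M phase genes were lower (median -0.37, -0.43 to -0.30), and 15 of its 16 immediate early genes were higher (median 0.47). For Krt8 the log2 ratio was 0.35 in thinned cells in place of 0.62, and for Cryab in the shared cluster it was -2.003 in place of -0.70 without the 5 cells with most of its UMIs.

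Podocyte-like cells had higher S100a6 (1.67, 1.41 to 1.98), the growth arrest gene Gadd45g (1.62, 1.42 to 1.84), Socs3, a feedback inhibitor of cytokine signalling (1.54), and Phlda1 (1.52) in the exposed library. Lower were mt-Nd3 (0.508), mt-Nd1 (0.619) and mt-Co2 (0.681), together with S100g (0.317, 0.233 to 0.426) and Fxyd2 (0.527), which are transcripts abundant in distal nephron segments. Tagln, which led 1 of the 2 podocyte-like clusters, was compared over all cells and stood at 129 and 170 CPM (1.32). In this class 15 of 16 immediate early genes were higher (median 0.26), as were 7 of 10 sterol and lipid synthesis genes (median 0.26, and 0.08 in thinned cells). The S100a6 log2 ratio was 0.17 in thinned cells in place of 0.69. Thinning kept 326 of 649 control and 282 of 419 exposed podocyte-like cells, so this value differs in the cells compared as well as in depth.

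Among the lowest genes of proximal tubule-like cells in the exposed library was Vnn1, which encodes pantetheinase (chromosome 10, 23894688 to 23905343), at 115 and 54.1 CPM (0.47, 0.38 to 0.578). The phosphate cotransporter gene Slc17a1 had a ratio of 0.525 (0.468 to 0.587), the fatty acid hydroxylase gene Cyp4a10 0.52 (0.448 to 0.602), Acaa2, an enzyme of mitochondrial fatty acid oxidation, 0.58 (0.511 to 0.656), and the organic anion transporter gene Slc22a6 (chromosome 19, 8618039 to 8628299) 0.596 (0.54 to 0.656). Higher were Itgb6 (1.69), Serpina6 (1.67), and the tubulin and tubulin-binding genes Tuba1b (1.63) and Stmn1 (1.62). Lars2, which led 1 of the 2 proximal tubule-like clusters, was 62.4 and 84.0 CPM over all cells (1.35). Of the nuclear-encoded oxidative phosphorylation genes, 35 of 36 were lower (median -0.29, -0.32 to -0.27), with Uqcrq at -0.45. The proximal tubule transport and metabolism list was mixed within the class, with 11 of 20 genes lower (median -0.03) and Slc5a2, the sodium-glucose transporter 2 gene, at 0.74. Over all cells, of which the class held a smaller share in the exposed library, 17 of 20 were lower (median -0.21). The G2/M phase list was higher at a median of 0.38 in 7 of 9 genes and the S phase list at 0.21. The share of cells with G2/M phase genes was not higher, at 17.0% and 15.8% in thinned cells and 34.1% and 33.7% without thinning. The immediate early median of 0.24 became -0.06 in thinned cells, and Serpina6 was at 0.20 on the log2 scale in place of 0.66 without the 5 cells with most of its UMIs. The cluster with a median of 67.2% mitochondrial UMIs, led by Slc34a1, Gpx3 and Miox and also by Yam1 and mt-Nd2, held 21.5% of this class in the control and 33.4% in the exposed library. Cells with over 25% mitochondrial UMIs made up 39.5% and 51.9%, and the mitochondrially encoded median of 0.16 turned to -0.26 (-0.29 to -0.25) without them.

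Loop of Henle and distal tubule-like cells showed the highest immediate early median, 0.50 (0.42 to 0.62), with 14 of 16 genes higher in the exposed library. Fosb stood at 61.4 and 135 CPM (2.21, 1.83 to 2.66), and the ratios of Btg2, Junb and Fos were 2.02, 1.85 and 1.81. Lars2 was also higher (2.02). Tmsb4x, which encodes the actin-sequestering thymosin beta 4 (0.562), the lysophospholipase gene Enpp2 (0.585), the galectin gene Lgals3 (0.628) and 1110008P14Rik (0.657) were lower, and the osteopontin gene Spp1, which is among the leading genes of 1 of the 2 clusters, was 319 and 253 CPM over all cells (0.793), although the difference of means of the authors' log values was 0.00925. All 36 nuclear-encoded oxidative phosphorylation genes were lower (median -0.21), and 9 of 13 sterol and lipid synthesis genes were higher (median 0.25). Each of the 17 measured G2/M phase genes was higher (median 0.38, 0.26 to 0.51), with the proliferation marker Mki67 at 1.02, but the G2/M phase median was 0.08 in thinned cells. Cells with over 25% mitochondrial UMIs made up 55.4% of the class in the control and 56.8% in the exposed library. The cluster led by Slc12a3 and Calb1 had a median of 53.1% mitochondrial UMIs. All values of this class therefore come largely from cells with a high mitochondrial share.

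Ureteric bud and collecting duct-like cells had higher Fosb (1.73, 1.54 to 1.93), Fos (1.55) and Jun (1.53), as well as Defb1 (1.91) and the proton pump subunit gene Atp6v1g3, a marker of intercalated cells (1.97, 1.66 to 2.35), in the exposed library. Of the immediate early genes 15 of 16 were higher (median 0.36), of the heat shock genes 10 of 10 (median 0.26), and of the sterol and lipid synthesis genes 9 of 12 (median 0.31), while 7 of 8 inflammatory genes were lower (median -0.30, -0.57 to -0.11), with the chemokine genes Cxcl1 at -1.22 and Cxcl2 at -0.98. Lower single genes were Sprr2f (0.31), S100g (0.544), Spp1 (0.587), mt-Nd3 (0.599) and Cdkn1c, a cell cycle inhibitor gene abundant in podocytes (chromosome 7, 143458339 to 143461050; 0.179, 0.127 to 0.248). For Cdkn1c 5 control cells held 72.8% of the UMIs, and without the top 5 cells of each library its log2 ratio was -0.82 in place of -2.08; for Defb1 it was 0.31 in place of 0.84 and for Sprr2f -2.38 in place of -1.42. Cells with over 25% mitochondrial UMIs made up 14.7% and 8.36% of the class, and the mitochondrially encoded median of -0.36 was -0.22 without them.

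Intercalated cell-like cells (227 and 106) had higher Hmx2, a transcription factor gene (2.73, 2.09 to 3.57), Ppp1r15a, a regulator of the integrated stress response (2.19), Btg2 (2.11) and Dnajb1 (1.92). Pendrin (Slc26a4), a marker used to name the class, was 5.28 and 8.86 CPM over all cells (1.68, 1.39 to 2.03). Lower were Timp3 (0.553), 2610016A17Rik (0.579), the metallothionein gene Mt2 (0.613), mt-Nd3 (0.648) and the calcium-binding protein gene Calb1 (0.648). Immediate early genes were higher in 12 of 15 cases (median 0.41) and heat shock genes in 10 of 10 (median 0.32). Without the 5 cells with most UMIs of the gene, the log2 ratio of Dnajb1 was 0.47 in place of 0.90 and that of Calb1 -1.32 in place of -0.62. Cells with over 25% mitochondrial UMIs made up 28.6% and 19.8% of the class, and the mitochondrially encoded median of -0.21 was -0.057 (-0.098 to 0.012) without them.

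Stroma-like cells had higher Ifi27l2a, an interferon-induced gene (41.9 and 126 CPM, 3.01, 2.63 to 3.45), the elastin gene Eln (chromosome 5, 134702593 to 134747323; 1.52), the tubulin gene Tuba1a (1.42) and Cyr61 (1.38) in the exposed library. Over all cells the matrix proteoglycan gene Dcn was 44.0 and 62.1 CPM (1.41) and the imprinted gene Dlk1 25.2 and 18.0 CPM (0.716), both markers of this class. Mitochondrially encoded genes were lower in 13 of 13 cases (median -0.59), with mt-Nd3 at a ratio of 0.464, mt-Nd1 at 0.58, mt-Cytb at 0.628 and mt-Atp6 at 0.633. Cells with over 25% mitochondrial UMIs made up 4.20% of the class in the control and 1.69% in the exposed library, and without them the median was -0.34 and the log2 ratio of mt-Nd1 -0.47 in place of -0.78. Of the G2/M phase genes 19 of 20 were lower (median -0.19, -0.23 to -0.14), of the S phase genes 16 of 20 (median -0.17), and of the inflammatory genes 7 of 9 (median -0.24), while 9 of 12 sterol and lipid synthesis genes and 15 of 20 extracellular matrix genes were higher (medians 0.25 and 0.12). The cluster marked by Birc5 and Cenpa, which are mitotic genes, held 28.5% of the class in the control and 21.8% in the exposed library. The inflammatory median was -0.08 in thinned cells, and the log2 ratio of Eln was 0.37 in place of 0.56 without the 5 cells with most of its UMIs.

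In pericyte, smooth muscle and renin cell-like cells (253 and 192), Eln was higher in the exposed library at 72.0 and 300 CPM (4.17, 3.10 to 5.68), with 80.7% of its control and 77.7% of its exposed UMIs in 5 cells each (14.5 and 69.2 CPM without them). Also higher were Sncg (2.25), the chemokine gene Cxcl12 (1.90) and Nrip2 (1.86). Renin (Ren1, chromosome 1, 133350510 to 133360325), the enzyme that starts the angiotensin cascade and a leading gene of this class, was compared over all cells and stood at 113 CPM in the control and 265 in the exposed library (2.34, 2.26 to 2.43). Cells with at least 10 Ren1 UMIs numbered 25 in the control (0.276%, 0.178 to 0.407) and 28 in the exposed library (0.51%, 0.339 to 0.736) and held 96.2% and 98.5% of its UMIs; without the 5 cells with most Ren1 UMIs in each library the log2 ratio was 0.67 in place of 1.16. The median Ren1 level of the cells with at least 10 Ren1 UMIs was lower in the exposed library (26403 and 15167 CPM). Lower in the class were S100g (0.143), Fabp4 (0.178), Fxyd2 (0.223) and A230065H16Rik (0.56), and Tnnt2, which leads 1 of its clusters, was 3.47 and 1.45 CPM over all cells (0.419). Fabp4 is a leading gene of the endothelium-like clusters. In the control, 5 cells held 78.3% of the UMIs of S100g, 62.6% of Fabp4 and 54.8% of Fxyd2, and in the exposed library 63.6%, 50% and 57.6%. Without these cells the log2 ratios were -1.57, -1.48 and -1.81 in place of -2.55, -2.09 and -1.94. For Tnnt2, 5 cells held 45.6% of the control and 80.5% of the exposed UMIs, and without them the levels were 1.89 and 0.284 CPM. Nuclear-encoded oxidative phosphorylation genes were lower in 31 of 36 cases (median -0.22) and cytosolic ribosomal protein genes in 71 of 81 (median -0.10). Without cells of high doublet score, the log2 ratio of Cxcl12 was 0.13 in place of 0.81 and that of S100g -1.01 in place of -2.55.

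Endothelium-like cells had higher interferon-stimulated genes in the exposed library. Isg15, a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818), stood at 47.6 and 149 CPM (3.12, 2.54 to 3.86), Rtp4 at 39.5 and 110 CPM (2.77, 2.198 to 3.52), and the immunoproteasome gene Psmb8 had a ratio of 1.69 (1.41 to 2.03). The interferon response list was higher in 9 of 11 cases (median 0.42, 0.31 to 0.50, percentile 100), with Ifit3 at 1.16 and Oasl2 at 0.82. Glycolysis genes were higher in 13 of 13 cases (median 0.20), sterol and lipid synthesis genes in 10 of 12 (median 0.34) and G2/M phase genes in 20 of 20 (median 0.39), including Cks2 (1.56), while Tuba1a was at 1.61. The angiogenic endothelium list stood at 0.03, inside the middle 95% of random lists, and the immediate early and heat shock lists at 0.03 and 0.01. Lower were mt-Nd3 (0.416), Stmn2 (0.44), S100a4 (0.459), Fxyd2 (0.372) and Ren1 (0.0252), the last from 5 control cells that held 99.5% of its UMIs. Only 1 control cell of the class held at least 10 Ren1 UMIs, of 395 in the class, so most of them lay in 1 cell. Cells with over 25% mitochondrial UMIs made up 6.06% and 2.02% of the class, and without them the mitochondrially encoded median was -0.34 in place of -0.66 and the log2 ratio of mt-Nd3 -0.79 in place of -1.22. In thinned cells the medians of the G2/M phase and the sterol and lipid synthesis lists were 0.06 and 0.02.

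Across classes, few genes differed the same way in at least 80% of the compared classes in which they had at least 50 UMIs. Yam1, a long non-coding RNA gene, was higher in 9 of 11 classes, with a median log2 ratio of 0.63 over classes and 793 and 1285 CPM over all cells (1.62, 1.60 to 1.65). Slc12a1, the sodium cotransporter gene of the loop of Henle, was lower in 4 of 5 classes (median -0.67). These included classes with only traces of it, such as podocyte-like (20.8 and 9.34 CPM) and stroma-like cells (8.49 and 1.30 CPM). In its own class, loop of Henle and distal tubule-like, it stood at 2980 and 2890 CPM (log2 ratio -0.044). Over all cells it stood at 261 and 244 CPM, a difference whose sign turned with the mean over cells and with the authors' log values. Haemoglobin transcripts, which belong to red blood cells, were lower in 6 of 7 classes for Hba-a1 and Hba-a2, 4 of 5 for Hbb-bt and 7 of 8 for Hbb-bs. The median log2 ratio over classes was -2.52 for Hbb-bs, -2.09 for Hbb-bt, -1.63 for Hba-a1 and -1.33 for Hba-a2. Over all cells the log2 ratios were smaller, at -0.62, -0.27, -0.35 and -0.32 in the same order. Each of these genes was higher by at least 0.5 in 1 class. Marker transcripts of 1 lineage found at low levels in classes of another lineage were likewise lower in the exposed library in 63 of 73 pairs of marker and class (21 genes, median log2 -0.40, -0.49 to -0.35), while in their own classes the same markers had a median of 0.06. Without cells of high doublet score, 57 pairs were lower and the median was -0.29.

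The last comparison asked how many cells carried transcripts of the G2/M phase of the cell cycle. Cells were thinned to 2554 UMIs each, which left out 2657 control and 983 exposed cells, and counted when at least 2 of the 20 genes were detected. Nephron progenitor-like cells reached 24.8% in the control (135 of 545) and 27.2% in the exposed library (97 of 357), a difference of 2.40 points (-3.37 to 8.34) within counting error; without thinning the shares were 37.9% and 44.0%. Classes of mainly differentiated cells, given for comparison, reached 23.9% and 17.4% in podocyte-like (-6.55 points, -12.9 to -0.0597), 17.0% and 15.8% in proximal tubule-like and 12.04% and 6.86% in intercalated cell-like cells. Median depths before thinning were 3842.5 and 4762 UMIs in progenitor-like, 2665 and 3205 in podocyte-like, 4560.5 and 4326 in proximal tubule-like, and 5395 and 7063 in intercalated cell-like cells. When thinned to 1000 UMIs, progenitor-like cells reached 11.4% and 9.97%, and podocyte-like cells 5.71% and 5.25%. At 2554 UMIs, differentiating nephron-like cells reached 81.2% and 78.0% (-3.18 points, -7.11 to 0.684). Their largest cluster had mitotic genes among its leading genes and progenitor markers detected, so the progenitor-like share may leave out cycling progenitors. Over the nephrogenic lineage the shares were 60.9% and 61.2%. Stroma-like cells reached 57.9% in the control and 39.4% in the exposed library (-18.5 points, -22.2 to -14.7). Thinning kept 1457 of 2455 control and 1172 of 1424 exposed stroma-like cells, and the difference was smaller at other depths, with 46.5% and 43.4% without thinning, and 32.2% and 25.3% when thinned to 1000 UMIs. The cluster shared with the loop of Henle reached 55.4% and 46.4% (-9.00 points, -15.8 to -2.13), loop of Henle and distal tubule-like cells 16.0% and 22.1% (6.03 points, 0.175 to 12.1, but -3.60 points when 1 gene sufficed), and endothelium-like cells 47.9% and 46.6% (-1.28 points, -8.49 to 5.95, and 5.63 points without thinning).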

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

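The tests on cells with over 25% mitochondrial UMIs, on stray RNA and on handling were chosen only after their results had been seen, while the comparison at the same mix of clusters was chosen before.

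In the nephrogenic lineage, genes of progenitor self-renewal were lower and genes of early differentiation higher in the exposed library. With both libraries at the same mix of clusters the early differentiation median was 0.078 (0.04 to 0.12), which argues against the mix of whole clusters as the cause for that list. A different mix of stages inside a cluster would not be removed by this weighting and was not tested. The largest cluster held 60.7% of the lineage's UMIs in the control and 56.7% in the exposed library. In it 8 differentiating nephron and 7 progenitor markers were detected. The self-renewal median at the same mix was -0.034 (-0.10 to 0.02), against -0.10 as measured, so for that list a different mix of clusters cannot be told apart from lower expression within clusters, because the limits include 0. Cited1 and Six2 stayed lower at the same mix (-0.36 and -0.35). A shift of the lineage towards differentiation after maternal diabetes is an open hypothesis, which 1 library per group cannot separate from differences between animals or in the moment of sampling.

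Mitochondrially encoded genes were lower in the nephrogenic lineage of the exposed library. Without cells with over 25% mitochondrial UMIs the median was -0.22 (-0.24 to -0.21), so such cells may account for part of the -0.39 measured but not for the whole. More stray RNA in the control library cannot be told apart from lower expression: markers of other lineages were lower in the exposed library too, with a median of -0.40, but a median of 35.1% of such UMIs in the control and 14.7% in the exposed library lay in cells with 5 or more of them, so doublets and stray RNA are mixed in this measure. Lower mitochondrial transcription after exposure, and a difference in cell quality between 2 frozen suspensions, both stay open.

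Immediate early and heat shock genes, which respond to dissociation as well as to stress in the animal, were higher in most epithelial classes of the exposed library. A handling difference acting alike on every class is argued against by the immediate early median of 0.031 in endothelium-like cells (-0.04 to 0.11), against 0.27 (0.24 to 0.31) in the nephrogenic lineage. The marker and class pairs gave no sign of more stray RNA in the exposed library, since 86.3% of them were lower there. Without cells of high doublet score their median log2 ratio was -0.29. Doublets and stray RNA are mixed in this measure, so it cannot decide on stray RNA alone. A handling difference to which classes respond unequally could give the same pattern and was not tested, and a response to maternal diabetes stays open beside it.

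Some list medians lay on opposite sides of 0 in different classes, and none of these differences was tested. The S phase list was higher by 0.442 in loop of Henle and distal tubule-like than in stroma-like cells. For the G2/M phase list, the median in endothelium-like cells exceeded that in the cluster shared by differentiating nephron and loop of Henle by 0.765, although in thinned cells these G2/M phase medians were 0.06 and -0.32 and the share of endothelium-like cells with G2/M phase genes differed by -1.28 points, within counting error. The mitochondrially encoded median was 0.932 higher in proximal tubule-like than in nephron progenitor-like cells, but without cells over 25% mitochondrial UMIs these medians were -0.26 and -0.32, with the same sign. The inflammatory list stood at 0.30 in differentiating nephron-like cells, with Cxcl10 at 0.69 and Vcam1 at 0.57, which was 0.603 above its median in ureteric bud and collecting duct-like cells.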

How the results depend on the processing

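Removal of cells with over 25% mitochondrial UMIs, totals without mitochondrially encoded genes, thinning to 1000 UMIs, removal by hybrid doublet score and removal of the 5 top cells were chosen only after the data were seen. No paired analysis was possible because each group has 1 library. No result has a replicate check, and counting error limits the small classes most.

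A value is called reversed where its sign changed and the counting interval of the reported value excludes 0; other sign changes are counted apart and are among the values that stayed within the interval or moved.

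Of 117 alternative values for 14 class shares, 103 stayed within the counting interval, 10 moved beyond it and 4 reversed. A further 4 changed the sign of a difference within counting error, of which loop of Henle and distal tubule-like cells stood at -0.332 without cells over 25% mitochondrial UMIs. The cluster shared by differentiating nephron and loop of Henle was not found in 5 of 9 alternatives, which give no value for it. With each library clustered on its own, differences in points were 4.27 for nephron progenitor-like, -8.66 for differentiating nephron-like (reversed), 4.47 for loop of Henle and distal tubule-like, -0.375 for macrophage-like (reversed), 0.564 for neutrophil-like (sign changed) and 0.984 for unnamed cells (reversed). There clusters with shared leading genes were named differently: that led by Irx1, Cxcl14 and Epcam was named differentiating nephron-like in the control (439 cells) and loop of Henle and distal tubule-like in the exposed library (368 cells), and that with Osr2, Cdh6 and Cpn1 among its leading genes differentiating nephron-like in the control (251 cells) and unnamed in the exposed library (149 cells). The control macrophage-like cluster (209 cells) also held the neutrophil markers S100a8 and S100a9 among its leading genes. The causes of the other differences were not tested. At Leiden resolution 0.5 they were 0.98 for differentiating nephron-like, 0.0466 for proximal tubule-like (reversed) and 1.90 for loop of Henle and distal tubule-like cells. After thinning they were -2.27 for proximal tubule-like, -0.915 for loop of Henle and distal tubule-like (sign changed), 2.90 for stroma-like (sign changed) and -4.34 for unnamed cells, and without cells over 25% mitochondrial UMIs -0.427 for unnamed cells.

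Of 91 values for shares of cells with G2/M phase genes, 79 stayed within the interval, 10 moved and 2 reversed. A further 17 changed the sign of a difference within counting error. Without thinning the differences were 3.67 points for all cells (reversed), -3.12 for stroma-like cells and 4.23 for the nephrogenic lineage, with changed signs at 6.18 for pericyte, smooth muscle and renin cell-like, 8.81 for ureteric bud and collecting duct-like and 5.63 for endothelium-like cells. Nephron progenitor-like cells changed sign to -1.80 with at least 1 gene, -0.954 with at least 3 and -1.42 at 1000 UMIs, where endothelium-like cells stood at 3.67. With at least 1 gene they were -3.60 for loop of Henle and distal tubule-like cells (reversed) and -10.6 for stroma-like cells, which stood at -6.92 when thinned to 1000 UMIs.

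Of 630 values for 70 list medians, 536 stayed within the counting limits, 92 moved and 2 reversed, and a further 8 changed sign. The immediate early list in proximal tubule-like cells stood at -0.062 in thinned cells (reversed). In the nephrogenic lineage the mitochondrially encoded list stood at -0.43 in thinned cells, -0.22 without cells over 25% mitochondrial UMIs and -0.42 with totals free of these genes, which gave 0.19 for the heat shock list and -0.012 for cytosolic ribosomal proteins (reversed).

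Of 1542 values for 129 genes, 1116 stayed within the interval, 423 moved and 3 reversed, all over all cells: Spp1 at 0.00925 and Slc12a1 at 0.034 by the authors' log values, and Slc12a1 at 0.039 by the mean over cells. TMM scaling kept the sign of 129 genes. The authors' log values, whose differences are on another scale, moved 112 of 129 genes by over 1.5 times, thinning 27, the mean over cells 18, removal of cells over 25% mitochondrial UMIs 13, adding 50 CPM 12, removal by doublet score 7, and removal of the 5 top cells 11 of 123.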

Other observations

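The further gene lists and the removal of cells with over 25% mitochondrial UMIs from the fatty acid comparison were chosen before their results were seen, although the patterns that prompted them had been seen in the same libraries.

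Since Acaa2, Cyp4a10 and Vnn1 were among the lowest genes of proximal tubule-like cells, a wider list of fatty acid oxidation genes was read in each class. In proximal tubule-like cells 19 of 22 measured genes were lower in the exposed library and 3 higher, with a median log2 ratio of -0.19 (percentile 0.05). Decr1 stood at -0.55, Acadvl at -0.39, Eci1 at -0.36 and Acadm at -0.33. The medians were 0.11 in differentiating nephron-like (percentile 99.94) and 0.14 in stroma-like cells (percentile 99.96), so the list was higher in those classes. Nuclear-encoded oxidative phosphorylation genes were lower in proximal tubule-like cells as well, by a larger median, so the lower values there were not particular to fatty acid oxidation. Without cells with over 25% mitochondrial UMIs, which left 397 control and 167 exposed cells, the median was -0.11 (-0.19 to -0.05) with 17 of 22 genes lower, which argues against such cells as the whole cause. A lower programme of fatty acid oxidation in the exposed proximal tubule may be worth following up as a hypothesis, and a proximal tubule at an earlier stage of maturation was not tested against it.

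In endothelium-like cells, where Isg15, Rtp4 and Psmb8 were among the highest genes, 11 of 12 further interferon-stimulated genes were higher in the exposed library, with a median of 0.37 (percentile 100). Xaf1 stood at 0.63, Psmb9 at 0.62, Eif2ak2 at 0.61 and Ifi35 at 0.58. The same list stood at 0.21 in stroma-like and 0.16 in podocyte-like cells. Its median was -0.03 (-0.11 to 0.11) in differentiating nephron-like cells. In ureteric bud and collecting duct-like cells it was -0.01 (-0.20 to 0.19), and in proximal tubule-like cells 0.04 (-0.11 to 0.29). In that order, only 8, 7 and 7 of the 29 listed genes were measured. The fixed interferon response list was higher in differentiating nephron-like cells, at 0.18 (0.03 to 0.32, percentile 99.55). It stood at 0.08 in ureteric bud and collecting duct-like and 0.002 in podocyte-like cells. The lists differ, so they cannot decide on differentiating nephron-like cells. An interferon response in endothelium-like cells of the exposed kidney may be one source of the higher values there. An infection or another difference between the animals was not tested.

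The unnamed cluster led by Upk3a, Krt19 and Upk1b, genes of the urothelium, held 41 control and 5 exposed cells. The amount of renal pelvis or ureter taken with each kidney is not given in the sources used here.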
